A study of Homo sapiens with 9 samples.

How the data were processed

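The study measured RNA from human primary monocytes on CodeLink 1-colour oligonucleotide arrays. Per the labels' protocols, monocytes were purified from blood mononuclear cells with a bead kit, kept for 1 h in a salt solution with 1% serum, and then given 60 nM leukotriene B4 (LTB4) or the ethanol vehicle at 0.019%. Per the series' design text, 1 treated and 1 vehicle sample were taken at each of 4 times (1, 3, 6 and 16 h), and each RNA was put on 2 chips. An untreated time zero sample makes 9 samples in all. The individual sample labels call the controls unstimulated, while the design text calls them vehicle controls; they are called vehicle here. Whether the samples share a donor is not given in the sources used here, so p-values measure only the spread between these samples.

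Per the labels' protocols, RNA was amplified once with T7 polymerase, labelled with biotin and hybridized. The authors deposited 1 linear intensity per probe and sample, so the 2 chips of each RNA had already been combined, in a way not given in the sources used here. The 9 deposited intensity columns have nearly the same distribution, with a median of 69.7 and a maximum of 116452 in each, as quantile normalization between samples leaves them; background correction and software are not given in the sources used here. There are no detection calls, and the number of arrays limits the precision. The table holds 53257 probes and 646 missing values, of which 372 are in the LTB4 3 h sample.

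Intensities under the 10th percentile (49.4) were set to it and log2 was taken, with no further normalization. Probes were tested if their mean log2 value over the 9 samples was above the median of such means (an intensity of 69.6) and if all 8 LTB4 and vehicle samples had a value, which left 26350 probes. The platform annotation gave 1 gene symbol for 23383 probes, several for 904 and none for 28970; updating symbols through gene identifiers changed 0 of them. Among tested probes 11111 had 1 symbol, for 9618 genes, and each gene was taken from its probe with the highest mean. No genome build is tied to the probes and no coordinates are given.

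Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. The LTB4 comparison had time point as a block, because the design text pairs 1 treated and 1 vehicle sample at each time, and left 3 residual degrees of freedom. The spread behind its p-values holds any change of the LTB4 effect with time. The culture comparison fitted a slope on log2 hours, per doubling of time, with treatment as a covariate and 5 residual degrees of freedom. It counts the LTB4 and vehicle samples of a time as independent, though both share any departure of that time from the line. Its p-values can therefore be too small. The change of the LTB4 effect with time was the interaction of treatment with centred log2 hours, with 2 residual degrees of freedom. At a single time there is 1 sample per treatment, so differences there are described without a test.

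Of 31 lists fixed by gene name, 22 were pathway lists and 9 were cell type markers. The 28 with at least 3 tested genes were tested with camera at a preset correlation of 0.01; with an estimated correlation no list was past the threshold in any of the comparisons. At single times a list's median was placed among 10000 random lists of the same size matched on mean expression.

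The named genes follow a rule. For the LTB4 and culture comparisons these are the 10 largest rises and 10 largest falls past the threshold, with the same sign at all 4 times for LTB4, filled where too few passed with the largest values of unadjusted p under 0.05, which are given as values that did not pass. To these come the 5 highest and 5 lowest differences at each time, 5 per direction for the change with time, up to 4 members with the largest change of each list described, and CCL2, CCL3, CCL7, CXCL8, IL1B, TNF, LTB4R, LTB4R2, ALOX5, PTGS2, SERPINB2 and CD36. Loci with only a clone or open reading frame name were passed over. Not every gene under the rule is named in the text.

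On simulated data made from the 26350 probes, the LTB4 fit recovered 5.97% of probes changed by 0.585 log2, 52.2% at 1 and 80.3% at 2, with 4 false calls. Each size was given to 66 or 67 probes. The simulated LTB4 effects were the same at all 4 times and the noise was independent between probes. These shares therefore do not hold for effects that change with time. The culture fit recovered 80.6% of slopes of 0.5 log2 per doubling, with 10 false calls. The interaction fit recovered 65.7% of slopes of 1, with 1 false call. For lists of 20 genes shifted by 0.5 log2 under LTB4, camera called 50 of 50 at the preset correlation and 26 of 50 with an estimated one. Of 1350 unshifted lists, 0 were called at the preset correlation. The simulated genes varied independently, so this does not test how often the preset correlation calls unshifted lists of correlated genes.

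Alternatives were other normalizations, filters, floors, variance models, array weights, thresholds, handling of missing values, leaving out each time point, and a fit without the time block. The test designs, lists, naming rule and most alternatives were fixed before the data were examined. Added after the data were seen were the 6 and 16 h effect alone, leaving out the probes far above all other samples at 3 h, leaving out the probes in the last grid rows, and the list test of the change with time. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.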

Results

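The data are 9 array profiles of human primary monocytes, the circulating precursors of tissue macrophages: 4 samples given LTB4, 4 given vehicle and 1 untreated sample at time zero. LTB4 is a lipid made from arachidonic acid that attracts leukocytes. The series asked how it changes monocyte transcription. Each sample had between 52885 and 53249 probe intensities. Single samples stand at each time and treatment, so the 4 time-matched differences are the only replication of the LTB4 effect, and log2 differences below are LTB4 minus vehicle.

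The first comparison asked which genes differed between LTB4 and vehicle over the 4 times. The highest mean differences among the listed chemokines were in CXCL2, CCL7 and CCL2, which attract neutrophils (CXCL2) and monocytes (CCL7 and CCL2). The mean log2 difference was 1.83 for CXCL2 (SE 0.46, adjusted p = 0.18), 1.82 for CCL7 (SE 0.62, adjusted p = 0.24) and 1.74 for CCL2 (SE 0.57, adjusted p = 0.23). All 3 were close to vehicle at 1 h and higher at 3, 6 and 16 h, so in 3 of 4 pairs. Without the 6 h pair the means were 1.06 for CCL7 and 1.11 for CCL2. The kinase gene MAP3K8, a regulator of inflammatory signalling, followed the same course with a mean of 1.52 (SE 0.44, adjusted p = 0.2). None of these passed the adjusted threshold, and limma called 0 of 26350 probes in either direction. The SE of a gene also holds any change of its difference over the 4 times, so a response limited to some times raises p. At unadjusted p under 0.05 there were 1557 higher and 2575 lower probes, 4132 in all, against 1318 in all by chance. The lowest adjusted p was 0.18. Another split of the samples, which parts 2 of the pairs, gave 3573 probes at unadjusted p under 0.05, so this excess does not exclude chance.

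Genes higher at all 4 times were led by RUBCNL, an autophagy regulator, at 1.35 (SE 0.18, adjusted p = 0.18), CDCP1 at 1.21 (SE 0.37) and HNRNPU at 1.09 (SE 0.3). They also held SLC23A2, a vitamin C transporter, at 1.02, PPARG, a lipid-sensing nuclear receptor, at 1.02, NPEPPS at 0.98, the protease gene MMP19 at 0.98 and the matrix gene THBS1 at 0.94. DIP2A (1.01) and POC5 (0.96) completed the 10. POC5 differed by 1.85, 0.1, 0.07 and 1.82 at 1, 3, 6 and 16 h, and its mean was 0.67 without 1 h and without 16 h. Some genes shared the sign only narrowly: MMP19 was at 0.04 and PPARG at 0.08 at 1 h, and EGR1, named below, at -0.08 at 6 h. For HNRNPU, SLC23A2, PPARG and DIP2A, and for COL8A1 below, the 1 other tested probe of each gene had the opposite sign. Genes lower at all 4 times were COL8A1 at -1.02 (SE 0.25), NUDT14 at -0.95, CAPN10 at -0.94 (SE 0.15), RAVER2, EGR1 and CMBL at -0.93, KCNK9 at -0.92, TMEM257 at -0.91, HOXD10 at -0.9 and SLAMF8 at -0.89. Several of these means were smaller without 1 pair: without 6 h CDCP1 was at 0.79 and PPARG at 0.63, without 1 h DIP2A at 0.54, without 3 h EGR1 at -0.61, and without 16 h HNRNPU at 0.69, HOXD10 at -0.59 and SLAMF8 at -0.58. Adjusted p for the 10 lower genes lay between 0.18 and 0.21. COL8A1, NUDT14, RAVER2, CMBL, TMEM257, HOXD10 and SLAMF8 shared a course over the samples, so they may not be separate changes. Each was lowest with LTB4 at 6 h, highest with vehicle at 1 h and 16 h, and fell most at 16 h. Olfactory receptor probes, described below, also had negative medians at 6 h (-0.18) and 16 h (-0.33). Whether the shared course is non-specific signal was not tested for these genes. Over all tested probes, 2303 were higher and 4293 lower at every time, or 25%, where independent signs would give 12.5%.

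Of the genes named in advance, CXCL8 had a mean difference of 0.56 (SE 0.35), CD36, a scavenger receptor, 0.46 (SE 0.26), PTGS2 0.16 (SE 0.12), ALOX5, the enzyme that starts leukotriene synthesis, -0.05 (SE 0.15), and TNF -0.22 (SE 0.13); none passed. Without the 6 h pair CXCL8 was at 0.13, PTGS2 at 0.1 and ALOX5 at 0.01; without 1 h CXCL8 was at 0.9 and ALOX5 at 0.08, without 3 h ALOX5 at -0.1, and without 16 h CD36 at 0.2 and ALOX5 at -0.19. The CCL3 and LTB4R probes were too dim to be tested, no probe carried the name LTB4R2 or SERPINB2, and IL1B shares its only probe with a second gene name and is not reported.

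Among gene lists, macrophage and lysosome genes were higher with LTB4 (camera, adjusted p = 0.0449, median 0.31 over 14 genes, adjusted p = 0.737 with an estimated correlation). Of the 14 members, 0 passed singly, over all probes or adjusted over the list alone. The largest were CTSL, a lysosomal protease, at 0.97, TFEC at 0.65, CTSK at 0.62 and GPNMB at 0.61. Without 1 h CTSL was at 1.49, without 6 h at 0.59, and without 3 h CTSK was at 0.315 and GPNMB at 1.14, or -0.09 without 16 h. The call was lost without the 6 h pair (adjusted p = 0.11) and without the 16 h pair (adjusted p = 0.096). Immediate-early genes were also called higher (adjusted p = 0.0449, median 0.26 over 25 genes, adjusted p = 0.737 with an estimated correlation), with 0 members past the threshold over all probes and 5 adjusted over the list alone. Its members went both ways: ZFP36, which promotes decay of cytokine mRNA, was at 0.68, RGS1 at 0.6 (0.37 without 6 h) and IER2 at 0.55, while the transcription factor gene EGR1 was at -0.93 (-0.61 without 3 h), with a 3 h value of -1.89 beside grid neighbours whose median was -1.55. This call was lost without the 1 h (adjusted p = 0.122), 3 h (0.152) or 6 h pair (0.11). Both calls were lost with no filter (adjusted p = 0.0692) and with fry (adjusted p = 0.283 for immediate-early genes and 0.537 for macrophage and lysosome genes).

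The other lists did not pass camera with all 4 pairs. By fry without direction, which asks for change either way, 8 lists passed for LTB4. The lowest were chemoattractant receptors (adjusted p = 0.00224), MHC class II genes and matrix genes (both 0.00632). Erythroid markers, a list of another blood cell type with 4 tested genes, were also among the 8 (adjusted p = 0.0206). Without the 1 h pair the NF-kappaB and scavenger receptor lists passed (adjusted p = 0.0452 each), and for 6 and 16 h alone, a test added after the data were seen, the scavenger receptor list did (adjusted p = 0.0127). The 17 tested NF-kappaB feedback and target genes had a median of 0.12 (adjusted p = 0.0574), with MAP3K8 at 1.52, IER3 at 0.53, SOD2 at -0.51 and NFKBIB at 0.43. The 19 scavenger receptor and lipid handling genes had a median of 0.28 (adjusted p = 0.0574). The 11 MHC class II and antigen presentation genes had a median of -0.23 (adjusted p = 0.114), with CD1D at -0.82, CIITA, the master activator of class II genes, at -0.5 and HLA-DMB at -0.48; the 1 other tested probe of CD1D and of CIITA had the opposite sign, and CIITA was at -0.3 without 16 h. The 13 chemokines had a median of 0.04 and a mean of 0.43 (adjusted p = 0.434): 6 members had unadjusted p under 0.05, and CCL18 was at -0.59. Cytokines had a median of -0.06, with CSF3 at -0.52, IL12B at -0.48, INHBA at -0.44 (-0.26 without 16 h) and HBEGF at 0.41 (0.15 without 1 h, 0.24 without 3 h, 0.68 without 6 h and -0.25 at 6 and 16 h alone). Leukotriene receptors and enzymes had a median of -0.05, with members going both ways: CYSLTR2 was at -0.38, CYSLTR1 at 0.37, LTA4H at -0.35 and MGST2 at 0.3, and without the 16 h pair CYSLTR1 was at -0.05, MGST2 at -0.2 and LTA4H at -0.21. MGST2 was at 0.73 without 3 h. Of the marker lists, monocyte markers had a median of -0.1 (adjusted p = 0.794), with LYZ at -0.75 and CD300E at -0.69.

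**Figure D1:**
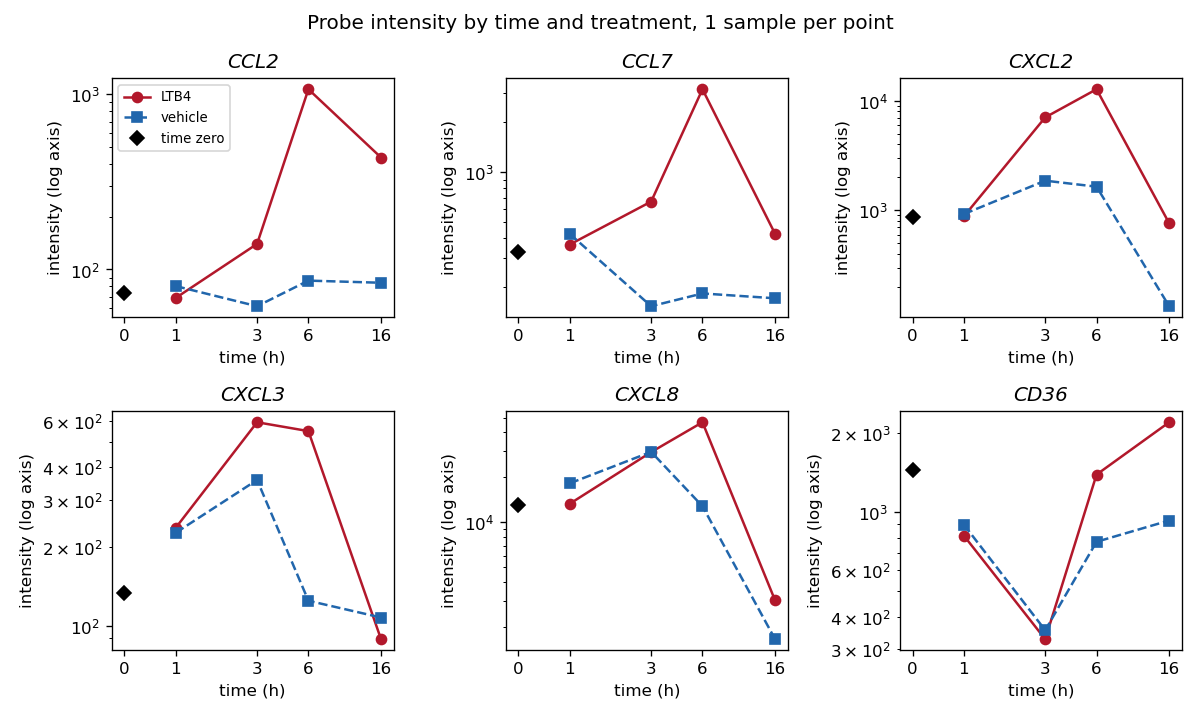
Probe intensity on a log axis against time in hours for CCL2, CCL7, CXCL2, CXCL3, CXCL8 and CD36, with circles for LTB4, squares for vehicle and a diamond for time zero, 1 sample per point. CCL7 stood at 3170 with LTB4 and 184 with vehicle at 6 h.

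The second comparison set each LTB4 sample beside its vehicle at the same time; with 1 sample each there is no replicate check. There are no detection calls, so where 1 of the 2 samples lies near the median intensity of 69.7, the size and rank of a difference are uncertain. The 6 h pair held the largest chemokine differences. CCL7 (probe 70017) was 4.1 log2 higher, CCL2 (probe 402090) 3.63, CXCL2 2.95, MAP3K8 2.73 and ASPH 2.6, with CXCL3 at 2.13 and CXCL8 at 1.86. CCL2 intensity at 6 h was 1070 with LTB4 and 86.4 with vehicle, and 73.8 at time zero. The lowest were STEAP4 at -1.94, POLRMT at -1.59, H4C4 at -1.44 and LYZ and VNN2 at -1.39. At 6 h, 365 probes were at least 1 log2 higher and 87 lower.

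At 16 h, 1204 probes were at least 1 log2 higher and 709 lower. The highest were WSB1 at 3.1, ZBTB11 at 2.7, GPNMB, a lysosomal glycoprotein, at 2.68, RASAL2 at 2.62 and CXCL2 at 2.51, and the lowest FBXW8 at -2.11, COL8A1 at -1.93, FGF11 at -1.9, TFF3 at -1.87 and DNAJC5G at -1.84. For RASAL2 the 2 other tested probes, and for COL8A1 the 1 other, had the opposite sign in the mean over times. Macrophage and lysosome genes had median differences of 0.55 at 6 h and 0.69 at 16 h, at the 100th percentile of matched random lists both times. Such percentiles, here and below, come from 1 pair of samples, ignore correlation between genes and are not adjusted for the number of lists. Scavenger receptor and lipid handling genes had medians of 0.2 (99.6th percentile) and 0.68 (100th percentile); NPC1, a cholesterol exporter, was 1.3 and 2.16 higher, CD163 1.28 and 1.89, and CD36 0.85 and 1.24. The interferon-stimulated list lay at the 99.9th percentile at 6 h with a median of 0.2. Platelet markers lay at the 0.38th percentile at 16 h with a median of -0.47, PPBP being at -0.95.

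At 1 h, 180 probes were at least 1 log2 higher and 126 lower. DIP2A (2.44), POC5 (1.85), CCR6 (1.82) and SSTR1 (1.72) were highest, against vehicle intensities of 65.7, 55.2, 65.7 and 151, and LDLRAD1 (-2.04), GRK1 (-1.84) and the stress gene HERPUD1 (-1.68) among the lowest; the other HERPUD1 probe had the opposite sign in the mean over times. Immediate-early genes lay at the 99.4th percentile (median 0.24) and MHC class II genes at the 0.36th (median -0.39). At 3 h, 644 probes were higher and 499 lower, and 208 differed by at least 3 log2 upward against 0 at 1 h, 2 at 6 h and 5 at 16 h. The highest, CDPF1 (9.81), DHX30 (8.88), ATXN10 (8.2), DSC2 (8.1) and MLH3 (7.8), were raised in the LTB4 3 h sample alone, and probes of this kind lay side by side on the array: 395 of the 644 higher probes were in the grid rows from 460 on, which hold 7.3% of the tested probes, and without these rows 249 were higher and 497 lower. Of the genes named here, RUBCNL, CMBL, ATXN10, DSC2, MLH3, LDLRAD1, DNAJC5G, GLO1 and TGFB1 have their probe in those rows. CDPF1 and DHX30 lay outside those rows, but within a second, smaller group of adjoining probes raised in the LTB4 3 h sample alone. Their grid neighbours had median 3 h differences of 1.18 (CDPF1) and 0.47 (DHX30). Both genes are still among the 249, so leaving out the last rows does not remove all such groups. Those rows also held 65 of the 126 lower probes at 1 h, LDLRAD1 among them. The lowest at 3 h were CILK1 (-2.67), HMGCS1 (-2.57) and SLC2A2 (-2.52), which were high in the vehicle 3 h sample alone, at intensities of 910, 293 and 359. Their grid neighbours had median 3 h differences of -0.63, -0.7 and -1.56, and the other HMGCS1 probe differed by -0.02.

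**Figure D2:**
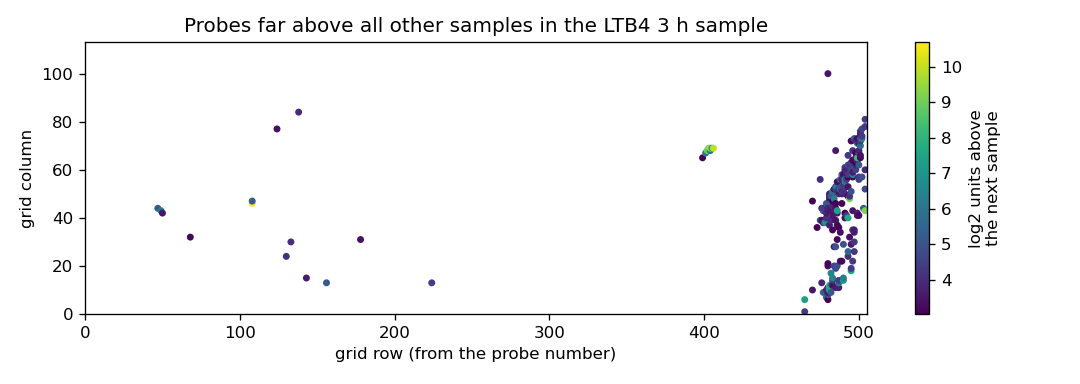
Array positions of the probes at least 3 log2 above every other sample in the LTB4 3 h sample, with grid row (horizontal) and grid column (vertical) read from the probe number and colour for log2 units above the next sample. Of 210 such probes, 188 lie in the rows from 460 on.

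**Figure D3:**
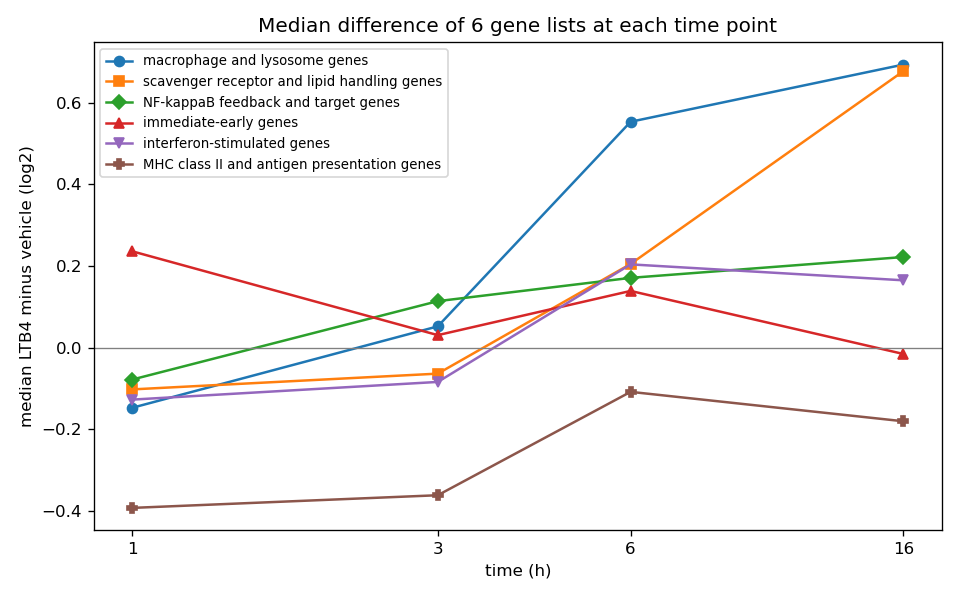
Median log2 difference between LTB4 and vehicle (vertical axis) at 1, 3, 6 and 16 h (horizontal axis) for 6 gene lists, 1 symbol per list, with no error bars because each time has 1 sample per treatment. Macrophage and lysosome genes lay at -0.15, 0.05, 0.55 and 0.69.

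The third comparison asked whether the LTB4 difference changed with time. The largest upward values per doubling of time were ZBTB11 at 0.87 (SE 0.13), WSB1 at 0.86 (SE 0.16), SLC30A7, CCL2 at 0.77 and GLO1 at 0.76, and the largest downward CHGB at -0.54 (SE 0.08), AFDN at -0.52, AEBP1 and PNN at -0.51 and GPR45 at -0.5. None passed: limma called 0 probes, with a lowest adjusted p of 0.291 and 1761 upward and 1112 downward probes at unadjusted p under 0.05. With the filter at the 75th percentile 38 probes passed upward. Without the 3 h pair 572 passed upward and 111 downward, with 1 degree of freedom fewer. The macrophage and lysosome list changed upward, by a median of 0.15 per doubling (camera, adjusted p = 0.0278, adjusted p = 0.788 with an estimated correlation); this test was added after the data were seen, and its call was lost without the 1 h pair (adjusted p = 0.243) or the 16 h pair (0.0628).

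The fourth comparison followed time in culture over LTB4 and vehicle samples together. Its p-values, those of the lists included, count the 2 samples of a time as independent and can be too small. The largest rises were in 2 matrix genes and 3 interferon-stimulated genes among others: THBS1 rose by 1.79 log2 per doubling of time (SE 0.46, adjusted p = 0.039), FN1, encoding fibronectin, by 1.77 (SE 0.19, adjusted p = 0.0043), HERC5 by 1.41 (SE 0.28), IFIT1 by 1.35 (SE 0.28) and MX1, an antiviral GTPase gene, by 1.27 (SE 0.25). RGL1 (1.52), PALLD (1.36), MS4A14 (1.18), RAB12 (1.12) and PPM1K (1.1) completed the 10 largest rises. The largest falls were in RGCC at -1.14 (SE 0.12, adjusted p = 0.0043), TAMALIN and RGS1 at -1.09, the growth factor gene TGFB1 at -1.05, the transcription factor gene KLF4 at -1.02, XBP1 at -0.89, the mitochondrial superoxide dismutase gene SOD2 at -0.88, ANXA1 at -0.87, BCL7A at -0.86 and PMEPA1 at -0.84. In vehicle alone, THBS1 intensity was 59 at 1 h, near the median of all probes, and 4970 at 16 h, and KLF4 differed by -4.25 log2. THBS1 was highest at 6 h, with intensities of 40800 with LTB4 and 17400 with vehicle against 7360 and 4970 at 16 h. For ANXA1, 1 of the 2 other tested probes had a slope of the opposite sign. Of these 20 genes, 6 passed without the 1 h samples: FN1, TAMALIN, RGS1, SOD2, ANXA1 and PMEPA1. Without 1 h THBS1 was at 0.39 (adjusted p = 0.82), MS4A14 at 0.63, TGFB1 at -0.55, KLF4 at -0.66 and PMEPA1 at -1.52. Without 16 h THBS1 was at 3.37, TGFB1 at -1.64 and PMEPA1 at -0.32 (adjusted p = 0.217); HERC5 was also lost there, and THBS1 without 3 h. In all, 1775 probes rose and 1802 fell, or 782 and 785 genes.

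Interferon-stimulated genes rose as a list (camera, adjusted p = 2.75e-06, median 0.6 per doubling, adjusted p = 0.773 with an estimated correlation): 13 of 27 rose, 0 fell, and 17 passed adjusted over the list alone. HERC6 rose by 1.07. Immediate-early genes fell as a list (adjusted p = 0.00389, median -0.19, adjusted p = 0.276 with an estimated correlation), with 6 of 25 members falling, 0 rising and 8 adjusted over the list alone, among them DUSP2 at -0.66 and PPP1R15A at -0.59. MHC class II genes fell (adjusted p = 0.0389, median -0.45, adjusted p = 0.773 with an estimated correlation), with 7 of 11 members falling, including HLA-DRA and HLA-DPA1 at -0.62 and HLA-DMB at -0.54. Cytosolic ribosomal protein genes fell (adjusted p = 0.0297, median -0.1, adjusted p = 0.773 with an estimated correlation), with 13 of 31 falling, RPS14 at -0.63, whose other probe had the opposite sign, and RPL19 at -0.51. Of lists that did not pass, matrix, protease and coagulation genes had a median slope of 0.07 (adjusted p = 0.489), with 2 of 15 rising and 1 falling; 5 of 17 NF-kappaB genes fell, among them TNFAIP6 at -0.75 and PTGS2 at -0.6; 3 of 14 macrophage and lysosome genes rose, CTSK at 0.74, TFEC at 0.64 and HEXA at 0.62 (1 other probe of TFEC and of HEXA had the opposite sign). Among 17 cytokines 2 rose and 3 fell (median slope -0.12), TNFSF13B rising by 0.6 and TGFB1 falling as above. Among monocyte markers CSF1R rose by 0.88, and S100A12 (-0.49) and LYZ (-0.45) fell. None of the members named in this paragraph passed without the 1 h samples. Without 1 h DUSP2 was at -1.09, HLA-DMB at -0.35, RPS14 at -1.09, RPL19 at -0.29, PTGS2 at -0.32, TFEC at 0.24 and LYZ at -0.18, and without 16 h DUSP2 at -0.18, RPL19 at -0.79, TNFAIP6 at -0.35, TFEC at 1.14, S100A12 at -0.14 and LYZ at -0.76.

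The count of probes moved with the samples used: 89 rose and 63 fell without the 1 h samples, 923 and 836 without 3 h, 1346 and 1050 without 6 h, 3853 and 4674 without 16 h, and 0 with the vehicle samples alone. The immediate-early (adjusted p = 0.161) and ribosomal calls (0.636) were lost without 16 h, and the MHC class II call without 1 h (adjusted p = 0.0878), 3 h or 16 h (both 0.0859). Other lists were called lower: NF-kappaB (adjusted p = 0.000995) and oxidative stress genes (0.00409) without 1 h, and oxidative phosphorylation genes with vehicle alone (0.0436). With fry, glycolysis and hypoxia (0.0249), amino acid and unfolded protein response (0.0299) and apoptosis genes (0.0378) were called lower and cell cycle genes (0.0299) higher.

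**Figure D4:**
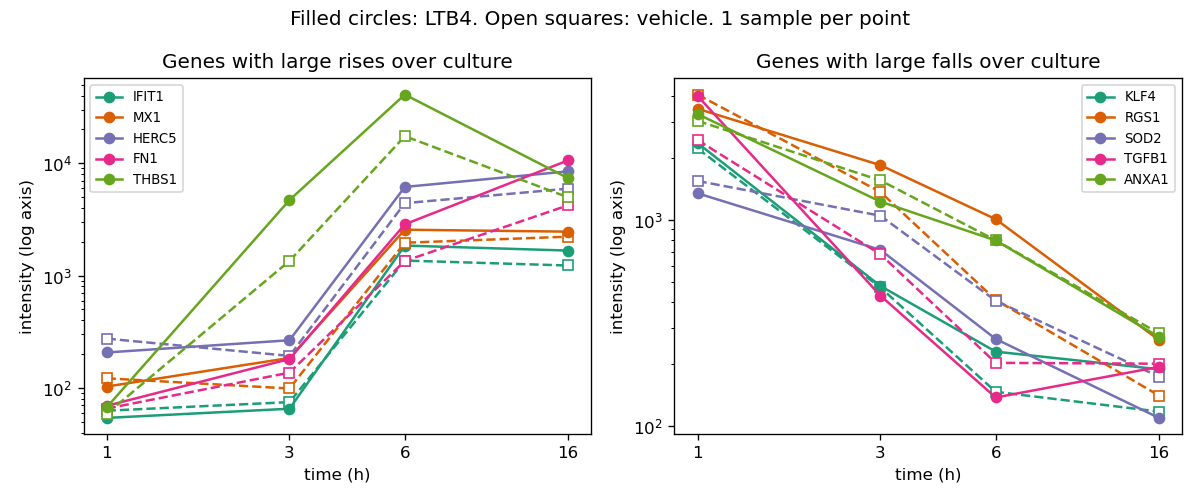
Probe intensity on a log axis against time in hours for 5 genes that rose (left) and 5 that fell (right) over culture, with filled circles for LTB4 and open squares for vehicle, 1 sample per point. FN1 and KLF4 moved in opposite directions, at 1.77 and -1.02 log2 per doubling of time.

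The last comparison set vehicle samples beside time zero, with 1 sample each and no test. At 1 h, 755 probes were at least 1 log2 higher and 949 lower than at time zero, at 3 h 998 and 563, at 6 h 1993 and 1461, and at 16 h 1609 and 1405. From time zero to vehicle at 16 h, intensity went from 79.4 to 4220 for FN1 and from 55.3 to 1230 for IFIT1, which lie near the median of all probes at time zero, and from 213 to 3840 for H4C4. It went from 3980 to 64.2 for RGCC, which is near that median at 16 h, while KLF4 differed by -5.4 log2 and RGS1 by -4.75.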

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

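The list test of the change with time and the count in the last grid rows were chosen after the data were seen; for the other tests the prediction was written before the test was run. Of 60 sets of 4 values examined for a value far from the other 3, 3 had one, where chance gives about 1 in 20. The 4 values of a set come from different times, so a gap can also be a time effect. The LTB4 3 h sample had 372 missing values against 37, 8 and 15 in the other LTB4 samples, and 210 probes at least 3 log2 above every other sample against 0. HNRNPU was 2.31 log2 higher with LTB4 at 16 h and between 0.54 and 0.83 at the other times. The LTB4 difference of macrophage and lysosome genes changed with time, by a median of 0.15 per doubling (camera, adjusted p = 0.0278, and 0.788 with an estimated correlation).

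For the 210 high probes of the LTB4 3 h sample, an array surface defect was set against a response to LTB4. If probe numbers give grid positions, 72.9% of these probes had another such probe among their 8 neighbours, against at most 8.57% in 1000 random placements, which a surface defect needs. The grid rows from 460 on held 188 of the 210 and 293 of the 372 missing values, though only 8.79% of all probes. The other 22 tested probes of the same genes had a median 3 h difference of 0.0857 log2, which argues against raised transcripts. A surface defect on a chip of that RNA is a candidate explanation that stays open. The probe numbers were taken as positions because differences of adjacent probes correlated across probes at 0.391 at 3 h. That value comes from the 3 h pair, which includes the LTB4 3 h sample itself. At 1, 6 and 16 h it was 0.1, 0.0717 and 0.0577, over 50490 pairs of adjacent probes. Outside 3 h the correlations were thus small, though above the 0.00658 at most for random pairs.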

How the results depend on the processing

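The LTB4 effect at 6 and 16 h alone, leaving out the extreme 3 h probes or the last grid rows, and the list test of the change with time were chosen after the data were seen. For LTB4 against vehicle, limma called 0 probes in either direction under each alternative fit run, including the one without the replicate block of time point; at unadjusted p under 0.05 there were 4132. A sign-flip test cannot pass with 4 pairs, since its smallest possible p is 0.125, and says nothing here. Of 196 counts under alternatives, 151 stayed within 1.5 times the reported count, 86 of them counts of 0 that stayed 0. Of 1269 LTB4 values of genes named for that comparison, named in advance or in the lists followed there, 7 changed sign. Of 993 culture slopes of genes chosen for the culture comparison 2 did. Genes chosen for the same sign at all 4 times cannot change sign when a pair is left out. Most others were chosen for a large change, so the low counts follow partly from the choice. Not every gene in the text is in these counts. The cause was not tested except where fewer probes or samples account for it.

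With no filter on dim probes, 828 probes rose and 764 fell over time in culture, and 191 were lower at 1 h and 1123 higher and 921 lower at 3 h. With the filter at the 75th percentile, which tests fewer probes, 29 were lower at 1 h, 227 higher and 169 lower at 3 h and 240 higher at 6 h, and 38 probes passed upward for the change of the LTB4 effect with time. Leaving out the last grid rows gave 61 lower at 1 h and 249 higher at 3 h.

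For time in culture, array weights gave 3603 rising and 4949 falling probes, an adjusted p under 0.10 gave 2790 and 3305, time zero with time as a rank 1159 and 1075, 16 h minus 1 h with time as a factor 3417 and 4144, and the vehicle samples only, with fewer samples, 0 and 0. Leaving out each time point in turn gave 89 to 3853 rising (without 1 h and without 16 h) and 63 to 4674 falling. For the change of the LTB4 effect with time it gave 0 to 572 upward and 0 to 111 downward, the highest without 3 h.

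For gene lists with LTB4, 2 were higher, against 0 with an estimated correlation, 0 with fry, 0 with no filter and 0 to 3 leaving out each time point, where the NF-kappaB and scavenger receptor lists passed without 1 h. For culture, 1 list rose and 3 fell, against 0 and 0 with an estimated correlation, 2 and 6 with fry, and 1 and 0 to 4 leaving out each time point. For the change of the LTB4 effect with time, 1 list passed, against 0 with an estimated correlation and 0 to 2 leaving out each time point.

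Among the values so counted, ALOX5 changed sign (-0.193 to 0.0778 leaving out each time point, 0.00717 without 6 h, and 0.0681 for 6 and 16 h alone). So did CYSLTR1 (-0.0547 to 0.542), MGST2 (-0.2 to 0.726) and GPNMB (-0.0876 to 1.14), the lowest without 16 h, and HBEGF (-0.247 for 6 and 16 h alone). The culture slopes of CSF3 (-0.891 to 0.013, the highest without 1 h) and TIMP1 (-1.04 to 0.162, the highest without 16 h) did too. Outside these counts other values changed sign, among them the LTB4 values of HMGCS1 (-0.181, and 0.614 without 3 h) and PECAM1 (0.176, and -0.047 without 1 h). The culture slope of STARD4 was -0.204, and 0.125 without 16 h. Signals near the floor of 49.4 limit what dim probes can show.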

Other observations

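No test in this part was chosen after its result was seen, though the patterns themselves were noticed in these data. Some groups and genes not described above are given here as values, and no list among them passed camera. By fry the glycolysis and hypoxia list passed over culture (adjusted p = 0.0249), and without direction it (0.0276) and the chemoattractant receptor list (0.00224) passed for LTB4. Heat shock genes had a median LTB4 difference of 0.44 at 16 h, at the 99.3rd percentile of matched random lists, with DNAJB1 at 1.13 and HSPA1A at 0.78. Cholesterol synthesis genes had a median of 0.33 at 16 h (98.1st percentile), with STARD4 and INSIG1 at 1.12, the INSIG1 probe lying in the last grid rows. Among glycolysis and hypoxia genes LDHA was lower at all 4 times (mean -0.66, SE 0.12, adjusted p = 0.18) and ADM, a vasodilator peptide gene, higher (0.65, SE 0.15, adjusted p = 0.18). Of chemoattractant receptors, ADGRE2 was at 0.56 (SE 0.11, adjusted p = 0.18) and CCR1 at 0.63. The lists of these genes lay at the 80.5th (glycolysis and hypoxia) and 85.6th percentile (receptors) at 16 h. In culture CD58 fell by 0.73 log2 per doubling, PECAM1 rose by 0.64 and FDPS rose by 0.59, and none of the 3 passed without the 1 h samples.

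CCL2, CCL7, CXCL2, CXCL3 and CXCL8 were between 1.86 and 4.1 log2 higher with LTB4 at 6 h. If probe numbers give grid positions, a surface defect is argued against by the 39 grid neighbours of these 5 probes, whose median 6 h difference was 0.0182. For cells of another blood type, the highest of the 8 non-monocyte marker lists, platelet markers, lay at the 74.7th percentile. These lists held from 1 (basophil and mast cell) to 7 (T cell) tested genes, too few to exclude such cells. PF4 and TREML1 in the platelet list were 0.04 and 0.21 log2 higher, TREML1 with its probe in the last grid rows. In the separate 3 h and 16 h pairs CCL2 (1.18 and 2.37), CCL7 (2.1 and 1.29) and CXCL2 (1.92 and 2.51) were also higher, which argues against a difference of the 6 h samples alone for these 3, but CXCL3 was at 0.72 at 3 h and -0.27 at 16 h, and CXCL8 at 0 at 3 h and 0.86 at 16 h. A response to LTB4 and cells of another blood type stay open for all 5, and a difference of the 6 h samples for CXCL3 and CXCL8.

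Differences at 6 h and 16 h correlated at 0.579 across probes, which are not independent replicates, while the other pairs of times lay between 0.0434 and 0.197. The 2 pairs share no sample. At both times 226 probes were at least 1 log2 higher, where independent lists would give 16.7, and 23 lower, where they would give 2.34. A trend with signal strength is argued against, since the correlation was 0.58 after a loess curve on the mean was removed. Non-specific signal that moves with the sample cannot be told apart from an effect on genes: 47 tested olfactory receptor probes, of genes taken beforehand as not expressed in monocytes, had a median of -0.18 at 6 h and -0.33 at 16 h, past the limit set beforehand only at 16 h. Within these 47 probes the 6 and 16 h differences correlated at 0.466.

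For the count of LTB4 probes, the real split gave 0 and all 32 splits of the 8 samples that can be fitted with the time block gave as many, the highest other also being 0. No split can give fewer than 0, so this comparison says nothing about chance. At unadjusted p under 0.05 the real split gave 4132 probes and the highest other 3573. Among the 8 splits that, like the real one, part all 4 time-matched pairs, the highest other gave 1920. With 8 such splits the real one comes first by chance in 1 of 8, so chance is not excluded for this count. The other splits part 2 pairs, and each of these gives the same counts as another, so fewer than 32 fits are distinct. For the gene lists, 9 of the 32 splits gave at least the real 2, and the highest other gave 7; among the 8 that part all pairs 3 did, with 2 as the highest other, so chance is not excluded. For time in culture, 4 of the 24 orders of the 4 times gave at least the real 3577 probes, the highest other giving 6512, so the count does not set the real order apart. Each order keeps the 2 samples of a time together, so this says nothing on whether the times differ; with time as a factor, 3417 probes were higher and 4144 lower at 16 h than at 1 h.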
